A study of Mus musculus with 12 samples.

How the data were processed

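Gene expression was measured with 1-colour Agilent microarrays in 12 samples of mouse hematopoietic progenitors, which the titles place in 4 groups of 3. Per the labels' protocols, multipotent progenitors (MPPs, sorted as lineage-negative c-kit-positive Sca-1-positive cells with intermediate Flt3) from 4 pooled mice per experiment were stimulated overnight with 50 ng/ml stem cell factor, 5 ng/ml interleukin-3 and 10 ng/ml interleukin-6, infected with a retrovirus carrying GFP and either Bach2 or Bach2 with its bZIP domain deleted, cultured for 2 days and sorted for GFP. The other 6 samples were LSK cells (lineage-negative, Sca-1-positive, c-kit-positive) from wild-type bone marrow and from bone marrow lacking Bach1 and Bach2. The protocol text is worded alike for all samples and describes only the infected MPPs, so the preparation of the LSK samples is not given in the sources used here. RNA went through 2 rounds of amplification and was labelled with Cy3, per the labels' protocols. One label field of the samples titled with the Bach2 vector names only a GFP vector. Their group was taken from the title.

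Per the file headers, the authors' scanner files were made with Agilent Feature Extraction 10.7.3.1, while the submitters' processing notes name version 9.1. The deposited values used here are spot intensities on a linear scale. The processed signal is a background-subtracted and detrended intensity, per the file headers, and was not normalized between arrays. The spot's median signal and the local background median are raw intensities, per the file headers. The deposited flags, of a kind other than a measurement, are values of 0 or 1 that mark spots well above background, saturated spots and outlier spots, per the file headers. The series' value table held the authors' processed values. All 755712 of them were equal to the processed signals of the scanner files, so it gave identical results. Its scale, centring and direction are those of the scanner files, and 0 columns lacked a sample.

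Each array held 59305 spots that were not controls, for 55681 probes. Spots with an outlier flag were left out, the spots of a probe were averaged on the log2 scale, and the 75th percentile of each array was subtracted, so that a level of 0 lies at that percentile. The files carry no gene names. The accession of a probe was matched without its version to RefSeq transcripts of mouse genes (assembly GRCm38.p6), which named 26413 probes and 20018 genes. A further 16194 probes carry chromosome regions of build mm9 and 13074 carry other accessions with no match, and these are unnamed here. The header's build differs from the table's assembly, so no coordinates are printed and the table's positions served only to find which genes neighbour each other. A gene was represented by the probe with the highest mean over the 12 arrays among probes with no outlier flag on any array. This left 36708 gene rows and lost 455. Genes were tested where the probe was well above background on all 3 arrays of at least 1 of the compared groups. No probe was saturated on any array.

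Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values) over the 6 arrays of each comparison, with Benjamini-Hochberg adjusted p under 0.05. For a gene not well above background on any array of a group, the fold is a bound. The bright group's mean was set against the mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. The 24 gene lists were tested with camera (inter-gene correlation preset at 0.01, adjusted over the lists of a comparison), and again with an estimated correlation and with fry. The lists cover granulocyte-monocyte progenitors, neutrophils, monocytes and macrophages, eosinophils, mast cells and basophils, dendritic cells, MHC class II, early lymphoid, B lineage and T and NK lineage genes, hematopoietic stem cells, erythroid cells, megakaryocytes and platelets, heme and oxidative stress, immediate early and heat shock genes, inflammatory cytokines, interferon response, S and G2/M phase, CDK inhibitors and p53 targets, cholesterol synthesis, glycolysis, stroma and endothelium, plasma cells, and Y-linked genes with Xist. The comparisons, lists, alternatives and the rule for named genes were set before the data were examined. That rule takes a panel of 30 genes, the 8 genes with the greatest differences in each direction among passing genes that have a symbol and whose replicates do not overlap (with fewer than 5 passing, the 8 with the greatest moderated t, as values), and the 4 members with the smallest p in the direction of each list that passed.

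Alternatives covered quantile normalization, normexp background correction with an offset of 50, the value table, the filter on dim probes, the mean over a gene's probes, the replicate number as a block, all 12 arrays in 1 fit, a mean-variance trend with robust moderation, array weights, a 2-fold threshold, the slide as a block and each array left out in turn. The normexp alternative was planned on mean spot signals and used median spot signals, which the files used here hold. Per the barcodes in the file headers, all 6 MPP arrays were on slide 1, with the 2 groups in different rows of it, so group and row cannot be told apart. Of the LSK arrays, 5 were on slide 2 and scan 2, and knockout replicate 3 was alone on slide 3 and scan 3. The labels state no pairing of the replicate numbers, so the main fits did not pair samples and the replicate block was an alternative. The deviations of arrays with the same replicate number did not correlate in every pair, which neither shows nor excludes pairing. The number of arrays limits the precision. On simulated data with 200 changed genes, the MPP comparison (22515 genes) recovered 27.8% of genes changed by 1, 81.5% of those changed by 2 and 96.4% of those changed by 4 on the log2 scale. The LSK comparison (20047 genes) recovered 15.5%, 57.9% and 92.4%. Of the calls made there, 4.81% and 4.67% were false. The simulated noise was normal, independent between genes and of equal SD in both groups, with no outlying array. These shares therefore do not measure the error in the real arrays, where such features may differ. A result that needs an item withheld for evaluation was left out.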

Results

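Expression was profiled in 12 samples of mouse bone marrow progenitors to ask how gain and loss of the transcription factor Bach2 change their lineage programs. Bach2 and its relative Bach1 bind DNA through a bZIP domain and are known as repressors. In the first comparison, 3 samples of multipotent progenitors (MPPs) infected with a Bach2 retrovirus were set against 3 samples infected with Bach2 lacking its bZIP domain. In the second, LSK cells, the bone marrow fraction that holds stem cells and multipotent progenitors, from mice without Bach1 and Bach2 (3 samples) were set against wild-type LSK cells (3 samples). No MPP group was titled as empty vector or uninfected, so an MPP difference can come from either form of Bach2. Rises and falls in MPPs are relative to the bZIP-deleted form. Gain below names the first comparison and loss the second, in which Bach1 is lacking too. Of the probes, between 52.5% and 70.8% were well above background on the MPP arrays and between 48.6% and 51.9% on the LSK arrays. Correlations within a group across genes well above background on all arrays lay between 0.982 and 0.994 in the MPP groups and between 0.985 and 0.992 in wild-type LSK cells. Those in the knockout went down to 0.967, because replicate 3 stood apart from replicates 1 and 2. Arrays did not always correlate best within their group. Knockout replicate 2 correlated at 0.990 with wild-type replicate 3 and at 0.984 with knockout replicate 1. In MPPs, Bach2 replicate 2 and bZIP-deleted replicate 2 correlated at 0.985, and Bach2 replicates 1 and 3 at 0.982. The labels do not say that the LSK samples came from separate mice. They give 4 pooled mice per MPP experiment, which alone does not show that each MPP replicate had a pool of its own. In both comparisons p-values therefore measure the spread between these samples. Levels are log2 signals relative to the 75th percentile of the array, differences are given ± SE on the log2 scale, and p-values are limma's with Benjamini-Hochberg adjustment unless stated.

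The targeted genes were examined first. In LSK cells the brighter Bach2 probe read 2.35 ± 0.14 (SD, n = 3) in wild type and 0.27 ± 0.68 (SD, n = 3) in the double knockout. All 3 knockout replicates lay below all 3 wild-type replicates, a 4.22-fold difference whose adjusted p was 0.175. A second Bach2 probe was not well above background on any LSK array. In MPPs it was so on 2 of 3 arrays with Bach2 and 1 of 3 with the bZIP-deleted form, and differed by 0.29, in the other direction than the brighter probe. Bach1 read 2.81 ± 0.40 in wild type and 2.74 ± 0.41 in the knockout (SD, n = 3). Which part of the genes was deleted and where the probes lie are not given in the sources used here, and a probe outside the deleted part checks nothing. In MPPs the same Bach2 probe read −3.80 ± 0.51 with the Bach2 vector and −2.01 ± 1.02 with the bZIP-deleted vector (SD, n = 3), with an adjusted p of 0.121. The difference passed in 2 of 17 alternatives. Both vectors carry Bach2 sequence, and both groups lay far below wild-type LSK cells in this probe, so it does not check the vector labels.

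With Bach2 in MPPs, 16 of 27 genes of heme turnover and the oxidative stress response fell and 6 of 10 MHC class II genes rose, and smaller shares of mature myeloid genes fell and of lymphoid genes rose. As lists, 14 of 24 passed camera and 0 with an estimated correlation (adjusted p from 0.0569 to 0.160 for the 14). Of 22515 genes tested, 376 were higher and 552 lower with Bach2 than with the bZIP-deleted form. At least 2-fold differences were found for 314 and 484 of these. The replicates of the groups did not overlap in any of the 928 genes, which adds no support because the same values chose these genes. Of all tested genes 18.7% showed such separation, where chance gives 10%. For 71 of the 928 the fold is only a bound. Among 199 other usable probes of changed genes, 6 had the opposite sign. Ranked by the measured difference, where genes with only a bound may stand too high, the first 8 lower genes with a symbol were Gzmb, a granule protease of cytotoxic and mast cells (−6.99 ± 0.51), Il1f9, a cytokine of the interleukin-1 family (at least 41.3-fold lower), Slc7a11, the cystine transporter that feeds glutathione synthesis (−6.33 ± 0.29), Lypd6b (−5.86 ± 0.19), the matrix protein gene Thbs1 (−5.63 ± 0.30), Rhou (−5.27 ± 0.19), the glutathione transferase gene Gsta3 (−5.20 ± 0.27) and the Tec family kinase gene Txk (at least 7.52-fold lower). Ranked in the same way, the first 8 higher genes were the adrenergic receptor gene Adra2a (6.31 ± 0.38), the immunoglobulin joining chain Jchain (at least 12.6-fold), the interleukin-18 receptor Il18r1 (4.33 ± 0.25), Slc2a7 (at least 5.91-fold), Khdc1a (3.88 ± 0.61), the transcriptional repressor gene Hic1 (3.78 ± 0.19), the sialyltransferase gene St8sia6 (3.59 ± 0.40) and Hepacam2 (at least 4.80-fold). Over 16 alternatives calls were lost in 4 for Slc2a7 (adjusted p up to 0.0917), 2 for Khdc1a (0.0670) and 1 each for Il18r1 (0.0528) and St8sia6 (0.136). The smallest differences over the alternatives were 4.58 for Adra2a, 2.64 for Il18r1, 2.35 for Khdc1a, 2.28 for St8sia6 and 1.87 for Hic1, and −5.21 for Gzmb, −5.58 for Slc7a11, −4.83 for Lypd6b and −3.94 for Rhou.

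Heme and oxidative stress genes formed the list with the smallest p. Of its 27 measured members 16 fell and 0 rose, with 22 lower when adjusted over the list alone, and the median difference was −1.05 (camera adjusted p = 5.53e-31; adjusted p = 0.0569 with an estimated correlation). Sulfiredoxin (Srxn1) fell by 3.94 ± 0.16, Osgin1 by 3.66 ± 0.18, the regulatory subunit of glutamate-cysteine ligase (Gclm) by 3.33 ± 0.17, and heme oxygenase 1 (Hmox1), which breaks down heme, by 1.86 ± 0.28. The Bach1 transcript itself was lower by 2.45-fold (adjusted p = 0.0206), a call lost in 6 of 17 alternatives (adjusted p up to 0.0987), and that of Hmox1 was lost in 2.

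Some genes of mature myeloid cells fell with Bach2. In the neutrophil list 5 of 15 measured members were lower and 0 higher (9 and 0 adjusted over the list alone; camera adjusted p = 1.09e-09; adjusted p = 0.110 with an estimated correlation). They included the collagenase gene Mmp8 (−3.27 ± 0.23), the granule protein gene Ngp (−4.66 ± 0.57), Wfdc21 (−2.60 ± 0.28) and Chil3 (−2.25 ± 0.34). In the monocyte-macrophage list 6 of 22 were lower and 1 higher (13 and 3 adjusted over the list alone; camera adjusted p = 1.56e-07; adjusted p = 0.110 with an estimated correlation), with falls of the macrophage receptor gene Trem2 (−2.55 ± 0.31), the receptor for macrophage colony-stimulating factor Csf1r (−1.45 ± 0.19), the mannose receptor Mrc1 (−1.35 ± 0.22) and lysozyme Lyz2 (−1.14 ± 0.20). In the granulocyte-monocyte progenitor list 5 of 17 fell and 0 rose (6 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.000144; adjusted p = 0.110 with an estimated correlation). Hexokinase 3 (Hk3, −3.48 ± 0.18), the Fc receptor gene Fcgr3 (−1.64 ± 0.20) and Igsf6 (−0.96 ± 0.18) were among them. Of the inflammatory cytokines and chemokines 6 of 16 fell and 1 rose (8 and 1 adjusted over the list alone; camera adjusted p = 6.75e-07; adjusted p = 0.0777 with an estimated correlation), among them Ccl3 (−4.49 ± 0.26), Ccl2 (−2.80 ± 0.22), Ccl9 (−2.09 ± 0.20) and Cxcl10 (at least 7.50-fold lower). Over 17 alternatives the calls of Igsf6 and Lyz2 were each lost in 8, that of Mrc1 in 4 and that of Chil3 in 2, and that of Cxcl10 was lost in 1 of 16. The myeloid regulators of the C/EBP family did not pass. Cebpa differed by −0.47 ± 0.26, Cebpb by −0.64 ± 0.20 and Cebpe by −0.03 ± 0.23, with adjusted p from 0.179 to 0.979. For Cebpd the adjusted p was 0.0673, with all 3 Bach2 replicates below the others. Over 17 alternatives calls were gained in 4 for Cebpd and in 1 each for Cebpa and Cebpb, all lower with Bach2. Cebpe was called in 1, where it was higher with Bach2 (0.45, adjusted p = 0.0229). That fit used array weights and called 9884 genes.

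Some antigen presentation and lymphoid genes rose. In the MHC class II list 6 of 10 members rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 7.31e-10; adjusted p = 0.0777 with an estimated correlation). The invariant chain Cd74 rose by 2.42 ± 0.19, H2-Aa by 2.14 ± 0.30, H2-Eb1 by 1.41 ± 0.18 and H2-Ab1 by 1.04 ± 0.16. In the early lymphoid list 8 of 23 rose and 1 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.000792; adjusted p = 0.0777 with an estimated correlation). The B cell adaptor gene Blnk (2.89 ± 0.38), Mn1 (2.67 ± 0.26), Ly6d (1.83 ± 0.26), terminal deoxynucleotidyl transferase Dntt (1.49 ± 0.20) and the cytokine receptor gene Flt3 (1.10 ± 0.20) were higher. Of the T and NK lineage list 3 of 16 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 6.93e-07; adjusted p = 0.0609 with an estimated correlation), namely the NK receptor gene Klrd1 (3.50 ± 0.49), the T cell factor Tcf7 (2.53 ± 0.23) and the T cell adaptor gene Lat (1.66 ± 0.23). In the B lineage list 2 of 17 rose and 0 fell, Blnk and Cd72 (1.42 ± 0.20), with 3 adjusted over the list alone (camera adjusted p = 0.00388; adjusted p = 0.145 with an estimated correlation). Of the dendritic cell list 5 of 15 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 3.61e-07; adjusted p = 0.0964 with an estimated correlation), with Ccr7 (2.48 ± 0.26), Ccl17 (2.63 ± 0.36) and the maturation marker Cd83 (at least 4.22-fold). Over 17 alternatives the call of Flt3 was lost in 6, that of H2-Ab1 in 5, that of Ly6d in 2 and those of H2-Eb1 and Ccl17 in 1.

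**Figure D1:**
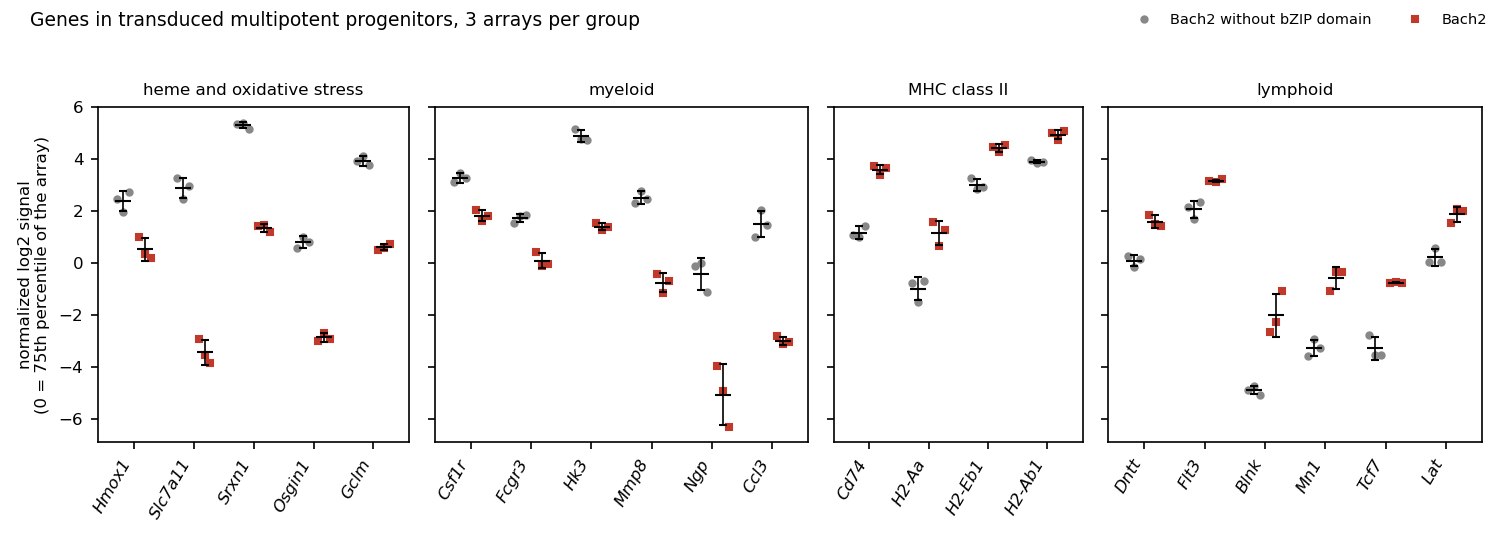
Normalized log2 signal of 21 genes in MPPs, with grey circles for the 3 arrays with bZIP-deleted Bach2, red squares for the 3 arrays with Bach2, and bars for mean and SD. In each gene shown the 2 groups do not overlap. The heme, stress and myeloid genes shown lay lower with Bach2, and the MHC class II and lymphoid genes shown higher.

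Genes of 4 further kinds passed as lists in MPPs. In the megakaryocyte-platelet list 7 of 22 members were lower and 1 higher (9 and 3 adjusted over the list alone; camera adjusted p = 0.000904; adjusted p = 0.110 with an estimated correlation). Thbs1, the chemokine genes Ppbp (at least 3.69-fold) and Pf4 (−2.39 ± 0.25) and the integrin gene Itgb3 (−1.97 ± 0.16) fell, while Gata1, a transcription factor of megakaryocytes and red cells, rose by 1.53 ± 0.24. Interferon response genes counted 3 higher of 22 and 0 lower (3 adjusted over the list alone), namely Gbp2 (1.54 ± 0.23), Xaf1 (1.09 ± 0.18) and Cmpk2 (0.98 ± 0.21), with a camera adjusted p of 0.00388 and an adjusted p = 0.160 with an estimated correlation. In the immediate early and heat shock list 4 of 21 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0234; adjusted p = 0.110 with an estimated correlation), with rises of Btg2 (1.44 ± 0.20), Jun (1.28 ± 0.26), Jund (1.00 ± 0.20) and Ier2 (0.79 ± 0.17). Over 17 alternatives the list lost its camera call in 4 (adjusted p up to 0.102), and single calls were lost in 11 for Ier2, 10 for Jund, 7 for Jun and 0 for Btg2. The glycolysis list passed downward (camera adjusted p = 0.00761; adjusted p = 0.110 with an estimated correlation) with 1 of 20 members past the threshold, the lactate transporter gene Slc16a3 (−1.05 ± 0.19), which was also the 1 call adjusted over the list alone. The list lost its call in 1 of 17 alternatives, Slc16a3, Xaf1 and Cmpk2 each in 7, Itgb3 (adjusted p up to 0.240) and Gbp2 (0.0551) each in 1, and Gata1 in 3. Members against their list included Fcgr1, Il1b and Klf6, named after their values were seen. Fcgr1 (1.56 ± 0.21) and Il1b (1.02 ± 0.17) rose, and Klf6 (−1.54 ± 0.18) fell.

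The other 10 lists did not pass camera in MPPs, with adjusted p from 0.0579 for S and G2/M phase to 0.760 for CDK inhibitors and p53 targets. Of the panel, 27 genes were measured and 9 passed, including Id2, an inhibitor of bHLH factors (1.89 ± 0.32), whose call was lost in 4 of 17 alternatives. Among the 18 others, Irf8 differed by 0.77 ± 0.17 (adjusted p = 0.0519), Gata2 by 0.66 ± 0.17, Ikzf1 by 0.55 ± 0.17, Mpo by 0.01 ± 0.17 and Il7r by 0.09 ± 0.50. Irf8 gained a call in 5 of 17 alternatives, and Gata2 and Ikzf1 each in 1. The count of changed genes was 450 with no filter on dim probes, 9884 with array weights, 531 without Bach2 replicate 2 and 534 without bZIP-deleted replicate 3. None of the 14 lists passed with an estimated correlation (limma camera; 2935 genes had an unadjusted p under 0.05), whereas fry, which asks whether the genes of a list move one way, passed 16 lists, these 14 among them.

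Loss of Bach1 and Bach2 in LSK cells gave few single-gene calls. Of 20047 genes tested, 5 were higher and 5 lower in the double knockout, and 2044 had an unadjusted p under 0.05. Only 3 of the 10 have a symbol. Minar1 was at least 3.14-fold higher, Fkbp6 at least 2.55-fold higher and Dync1i1, a dynein intermediate chain gene, at least 8.20-fold lower. Over 16 alternatives the call was lost in 10 for Dync1i1 (adjusted p up to 0.174), 7 for Fkbp6 (0.0880) and 2 for Minar1 (0.0880). The files do not pair the others with names. Among them, transcripts ENSMUST00000103335 (at least 69.0-fold) and ENSMUST00000103303 (at least 12.6-fold) were lower and ENSMUST00000098289 (at least 5.45-fold) was higher. For 7 of the 10 the fold is only a bound. Next by moderated t, and not past the threshold, came Gclm (1.85 ± 0.19, adjusted p = 0.0634), Lmo1 (1.45 ± 0.20), Itga2b (1.41 ± 0.21), Gja1 (1.88 ± 0.28), Vash2 (1.31 ± 0.20) and Aldh1a1 (2.60 ± 0.40) with positive differences. On the negative side were Zfp503 (−3.77 ± 0.40, adjusted p = 0.0634), Rftn2 (−1.58 ± 0.18), Vsig2 (−2.27 ± 0.29) and Zp1 (−1.77 ± 0.25), and with only a bound Ndnf (at least 2.36-fold), Msmp (at least 1.45-fold) and Xkr6 (at least 1.41-fold), which were not well above background on any knockout array. Of the panel, 29 genes were measured and 0 passed. Hmox1 differed by 1.36 ± 0.42, Cebpa by 1.04 ± 0.43, Cebpd by 0.72 ± 0.28 and Tcf7 by 1.44 ± 0.60, with adjusted p from 0.421 to 0.489.

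As lists under camera, LSK cells without Bach1 and Bach2 lay lower in plasma cell and interferon response genes and higher in S and G2/M phase, granulocyte-monocyte progenitor, and mast cell and basophil genes. Stem cell and early lymphoid genes passed downward only with knockout replicate 3 included. With an estimated correlation 0 of these 7 lists passed (adjusted p from 0.715 to 0.890), and with fry 0. No member of these 7 lists passed over all genes, so members are given as values. The plasma cell list had a median of −1.72 over 9 measured members, of which 6 were lower adjusted over the list alone (camera adjusted p = 2.39e-06; adjusted p = 0.715 with an estimated correlation). Its members Jchain (−2.56 ± 0.39), the B cell maturation antigen Tnfrsf17 (−3.56 ± 0.73), Mzb1 (−2.94 ± 0.66) and Irf4 (−1.83 ± 0.40) had knockout replicates below all wild-type replicates. The S and G2/M phase list had a median of 0.39 with 29 of 34 members positive (camera adjusted p = 4.87e-05; adjusted p = 0.725 with an estimated correlation), as in Kif11 (0.84 ± 0.25), Plk1 (0.59 ± 0.19), Mcm5 (0.52 ± 0.20) and Top2a (0.47 ± 0.18). The granulocyte-monocyte progenitor list had a median of 0.82 (camera adjusted p = 0.00121; adjusted p = 0.725 with an estimated correlation) and 0.36 without replicate 3 of the knockout, with Igsf6 (1.70 ± 0.58), Csf1r (1.32 ± 0.34), Irf8 (1.15 ± 0.31) and Hk3 (0.93 ± 0.30). The mast cell and basophil list, median 0.62 (camera adjusted p = 0.0158; adjusted p = 0.725 with an estimated correlation), held Gzmb (3.43 ± 0.88), Prss34 (2.57 ± 1.25), Mcpt8 (2.04 ± 0.79) and Cpa3 (1.37 ± 0.48). Without replicate 3 of the knockout these were 2.36, 2.38, 1.74 and 0.78. The smallest Prss34 difference over the alternatives was 1.07. The interferon list had a median of −0.23 (camera adjusted p = 0.0327; adjusted p = 0.725 with an estimated correlation), with Oas2 (−0.71 ± 0.31), Rtp4 (−0.57 ± 0.24), Usp18 (−0.53 ± 0.22) and Ifit1 (−0.49 ± 0.20). In these 4 lists 0 members passed adjusted over the list alone. Over 17 alternatives the interferon list lost its camera call in 4 (adjusted p up to 0.283) and the mast cell and basophil list in 1 (0.0708).

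Stem cell and early lymphoid lists moved with knockout replicate 3, the array on a slide of its own. The stem cell list had a median of −0.24 (camera adjusted p = 0.00859; adjusted p = 0.890 with an estimated correlation), with Ndn (−1.15 ± 0.40), Hlf (−0.81 ± 0.37), Procr (−0.64 ± 0.34) and Gfi1b (−0.51 ± 0.27). The early lymphoid list had a median of −0.28 (camera adjusted p = 0.0342; adjusted p = 0.890 with an estimated correlation), with Ccr9 (−1.82 ± 0.57), Ly6d (−1.27 ± 0.66), Mn1 (−1.22 ± 0.41) and Blnk (−1.04 ± 0.36). In both 0 members passed adjusted over the list alone. With the slide as a block, which leaves the 5 arrays of 1 slide, the medians were −0.04 and −0.11 and the adjusted p 0.572 and 0.896. The granulocyte-monocyte progenitor median fell to 0.36 (adjusted p = 0.0271). The medians of the other lists within that slide were −1.34 for plasma cell, 0.26 for S and G2/M phase, 0.56 for mast cell and basophil and −0.22 for interferon genes, with adjusted p of 1.30e-06, 0.00381, 0.0135 and 0.0312. Heme and oxidative stress genes, with a camera adjusted p of 0.0566 over all arrays, had a median of 0.17 and an adjusted p of 0.0146 there, and glycolysis genes 0.24 and 0.0311. Over all arrays neither list passed with an estimated correlation (adjusted p = 0.715 and 0.890) or with fry (0.104 and 0.402). Over 17 alternatives the early lymphoid list lost its call in 7 and the stem cell list in 2. The slide as a block and leaving out knockout replicate 3 are the same fit, so the 2 losses of the stem cell list are 1 fit counted as 2. The value table repeats the main fit and could not lose a call.

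**Figure D2:**
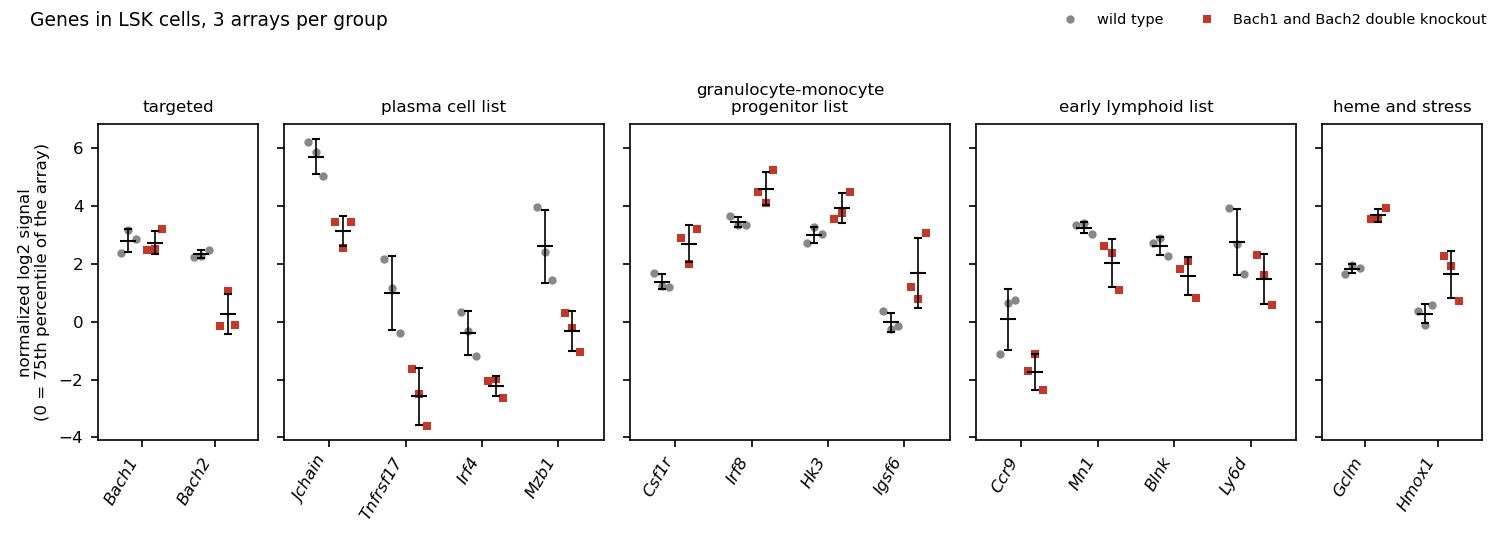
Normalized log2 signal of 16 genes in LSK cells, with grey circles for the 3 wild-type arrays, red squares for the 3 knockout arrays, and bars for mean and SD. Jchain lay at 5.72 in wild type and 3.16 in the knockout on average, and none of the genes shown passed the threshold over all genes.

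Counts of single genes in LSK cells depended on few arrays. The 10 calls became 3 with the slide as a block, where Minar1 passed (adjusted p = 0.0321) and Fkbp6 (0.0568) and Dync1i1 (0.0602) did not, 0 when probes had to be well above background on all 6 arrays, and 83 when all 12 arrays shared 1 fit. Leaving out 1 array gave 0 calls without wild-type replicate 3, 4 without wild-type replicate 1, 5 without wild-type replicate 2, 6 without knockout replicate 1, 16 without knockout replicate 2 and 3 without knockout replicate 3.

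Gain and loss were compared over the 19037 genes tested in both, with no array in common. Pearson's r across genes was −0.151 and Spearman's rho −0.151, where genes are not independent replicates. With no filter on dim probes they were −0.0592 and −0.0737, and with 1 array left out rho lay between −0.242 and −0.0509. Of 792 genes changed in MPPs and tested in LSK cells, 495 (62.5%) had the opposite sign in the knockout, against 53.04% of all 19037 genes. The 318 genes higher with Bach2 than with the bZIP-deleted form lay lower as a set in knockout LSK cells, with a median of −0.25 (camera adjusted p = 1.22e-05; p = 0.161 with an estimated correlation). The 474 genes lower with Bach2 lay higher, with a median of 0.10 (camera adjusted p = 0.0320; p = 0.318 with an estimated correlation). That call was also lost with all 6 arrays above background (0.0613), with the replicate number as a block (0.0568), and without wild-type replicate 3 (0.158), knockout replicate 1 (0.0999) or knockout replicate 2 (0.405). Both LSK genes called higher and tested in both comparisons were lower with Bach2 in MPPs, where 0.0498 would be shared by chance (2-sided Fisher's exact p = 0.000619). They are probes for AK085126 and for an unnamed region, and within the slide neither was called in LSK cells (adjusted p = 0.0887 for both). Of 102 named genes tested in both, 64 had opposite signs and 38 the same sign. Gclm (−3.33 in MPPs and 1.85 in LSK cells), Jchain (at least 12.6-fold higher, and −2.56) and Gzmb (−6.99 and 3.43) had opposite signs, while Tcf7 (2.53 and 1.44), Id2 (1.89 and 0.51), Gata1 (1.53 and 1.04) and Irf8 (0.77 and 1.15) had the same sign. Within the slide, without knockout replicate 3, the LSK differences were 1.73 for Gclm, −2.72 for Jchain and 2.36 for Gzmb. They were 1.34 for Tcf7, 0.17 for Id2, 0.09 for Gata1 and 0.84 for Irf8. None of these 7 genes passed in LSK cells, where the adjusted p was 0.0634 for Gclm, 0.153 for Jchain and 0.380 for Gzmb, and Irf8 did not pass in MPPs either. The 3 lists that passed camera in both comparisons went in opposite directions. Granulocyte-monocyte progenitor genes had medians of −0.35 in MPPs and 0.82 in LSK cells, early lymphoid genes 0.38 and −0.28, and interferon response genes 0.26 and −0.23. Within the slide the LSK medians were 0.36, −0.11 and −0.22, and over 17 alternatives the LSK calls were lost in 0, 7 and 4. None of them passed with an estimated correlation (adjusted p of 0.110 and 0.725, 0.0777 and 0.890, and 0.160 and 0.725). Plasma cell genes, with the greatest LSK median, had a median of 0.08 in MPPs, where Irf4 and Jchain rose and 0 members fell (camera adjusted p = 0.236; fry adjusted p = 0.0195, upward).

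**Figure D3:**
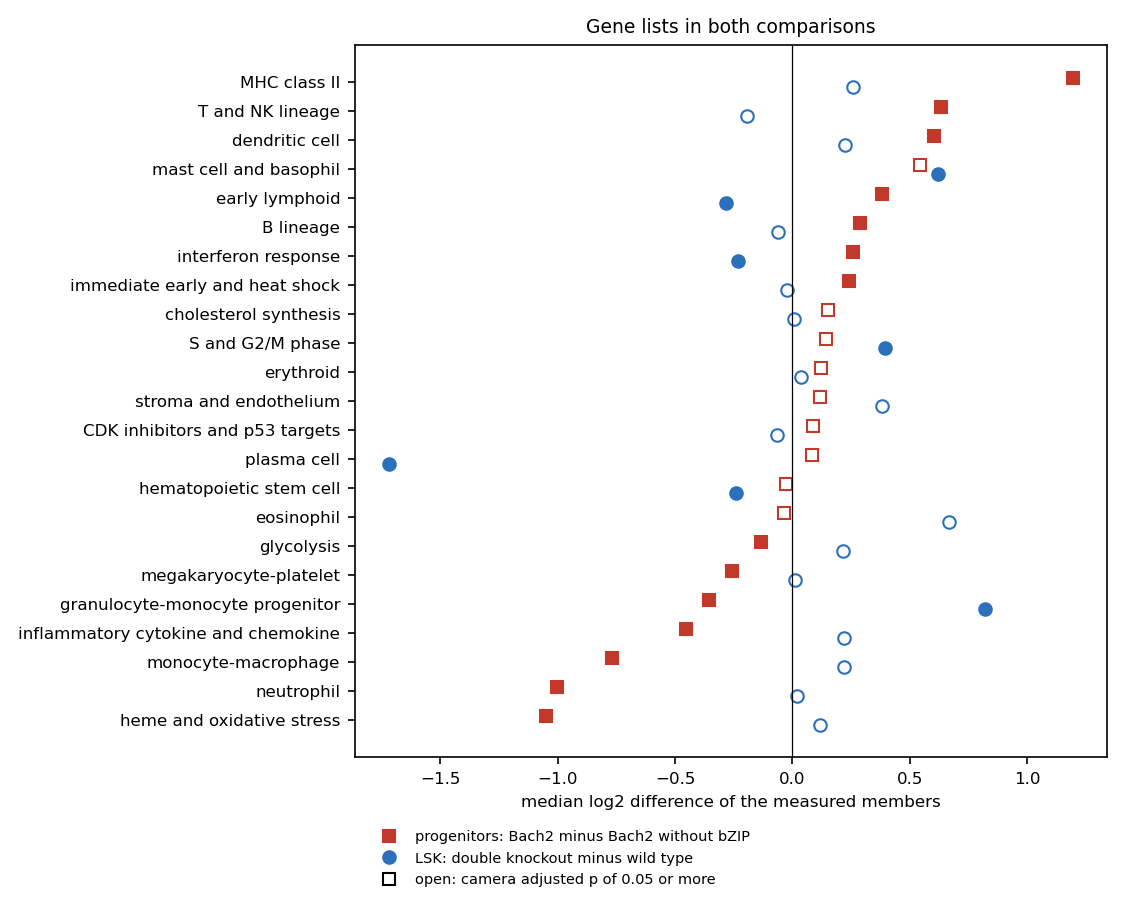
Median log2 difference of the measured members of 23 gene lists in MPPs (Bach2 minus bZIP-deleted Bach2, red squares) and in LSK cells (double knockout minus wild type, blue circles), filled where the camera adjusted p was under 0.05. The heme and oxidative stress median was −1.05 in MPPs and 0.12 in LSK cells, and that of the plasma cell list 0.08 and −1.72.

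Genes near the targeted loci can carry variants of the stem cell strain in which a knockout was made. Only genes with a symbol could be placed, which covers 3 of the 10 LSK calls. Within 10 Mb of Bach1 or Bach2, 0 of 130 tested genes passed, which allows a share of up to 2.31%, against 3 of 12607 elsewhere (2-sided Fisher's exact p = 1.0; limma). With so few placed calls this test could hardly tell the shares apart, and the calls without a symbol were not checked. At an unadjusted p under 0.05 there were 12 of 130 (9.23%) and 1259 of 12607 (9.99%), with a Fisher's exact p of 0.884.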

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

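Array weights, 2 windows and other settings were planned. Leaving out replicate 1 of both MPP groups, the unadjusted threshold near the loci and the estimated correlation for the sets of MPP genes were chosen after seeing the data. A direction is read only for a result called in at least 1 of the compared fits. The 928 MPP genes became 938 with quantile normalization, 939 with normexp, 788 with all 6 arrays above background, 912 with mean probes, 655 with all 12 arrays, 943 with a trend, 798 at 2-fold and 752 without replicate 1 of both groups. They became 450 (147 higher, 303 lower) with no filter, where 36708 genes were tested, and 9884 (6339 and 3545) with array weights, where the cause was not tested. Leaving out 1 array gave 531 to 801, with the lowest counts without Bach2 replicate 2 and without bZIP-deleted replicate 3. The 14 MPP lists became 0 with an estimated correlation and 14 to 15 with 1 array left out. Cebpe in MPPs turned to 0.45 (adjusted p = 0.0229) with array weights, the only named gene that reversed (adjusted p over its alternatives 0.0229 to 0.998). The 10 LSK genes became 4 with no filter, 0 with all 6 arrays above background (limma; 1859 at an unadjusted p under 0.05), 83 with all 12 arrays, which pools the spread of both cell types, 17 with a trend, 3 with the slide block and 0 to 16 with 1 array left out. The 7 LSK lists became 0 with an estimated correlation, 0 with fry and 4 to 8 with 1 array left out, with 4 without knockout replicate 2. The correlation of gain and loss was −0.0592 with no filter and −0.203 to −0.105 with 1 array left out. The set of genes higher with Bach2 in MPPs had an adjusted p of 0.318 in LSK cells with an estimated correlation and 8.80e-09 to 0.000788 with 1 array left out. The set lower with Bach2 in MPPs had 0.0613 with all 6 arrays above background, 0.318 with an estimated correlation and 0.000107 to 0.405 with 1 array left out. It lost its call without wild-type replicate 3 (0.158), knockout replicate 1 (0.0999) or knockout replicate 2 (0.405). Near the loci 12 genes passed unadjusted. Of the 1511 comparisons of a named MPP gene with an alternative 1365 left the call as it was, 112 lost a call and 33 gained one. For LSK genes 1154 of 1195 left it as it was, 19 lost and 22 gained one. Uncalled genes could turn sign within these counts, such as Mpo in MPPs (−0.118 to 0.140) and Elane in LSK cells (−0.608 to 0.991). The counts include the value table, which repeats the main fit. In LSK cells the slide block and leaving out knockout replicate 3 are the same fit counted as 2. The causes of these moves were not tested.

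The replicate numbers were tried as a replicate block. Deviations of equally numbered MPP arrays correlated at 0.191, 0.202 and −0.0909 and those of LSK arrays at 0.269, −0.0379 and 0.0124. For MPP replicates 1 and 2 and LSK replicate 1 the best partner was the equally numbered array. These few values neither show nor exclude that equal numbers mark paired samples. With the block 883 MPP genes and 0 LSK genes passed (limma; 2301 LSK genes at an unadjusted p under 0.05), and 15 MPP and 8 LSK lists passed. The correlation of gain and loss was −0.151, and the set lower with Bach2 in MPPs had a camera adjusted p of 0.0568.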

Other observations

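The tests of symbol families, of explanations and of splits in this part were chosen after the results were seen, except that of mature myeloid lists in knockout replicate 3, while the comparisons, lists and the correlation of gain and loss they refer to were planned. Families of genes whose symbols share their leading letters were tested with camera in MPPs, 411 families of at least 5 members, of which 12 passed. None passed with an estimated correlation (lowest adjusted p = 0.994), and 0 medians changed sign with quantile normalization or normexp. Mu-class glutathione transferases (Gstm) had a median of −1.09, with Gstm1, Gstm2 and Gstm3 lower with Bach2, and the Abcc transporters a median of −0.59, with Abcc1, Abcc2 and Abcc3 lower. C-type lectin genes had a median of −0.39 with 6 of 19 lower, of which Clec4d fell by 3.14 ± 0.27 and Clec5a by 3.02 ± 0.50. Guanylate-binding protein genes (Gbp) had a median of 0.79 with Gbp2 and Gbp4 higher. Among genes whose symbol starts with Bcl, Bcl11a (1.25), Bcl6 (1.42), Bcl2a1c (2.13) and Bcl2a1d (1.84) were higher. The mast cell and basophil list split in MPPs, with 4 members higher (Cpa3, Mcpt8, Ms4a2 and Hdc) and 3 lower (Mitf, Il4 and Gzmb), and the eosinophil list held 2 higher members, Il5ra (1.57) and Siglecf (1.83).

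In LSK cells 3 of 389 such families passed, all with negative medians and 0 members past the threshold, and none passed with an estimated correlation (lowest adjusted p = 0.973). They were the lymphoid GTPase genes Gimap (median −0.71 over 8), the Speer genes (−2.01 over 5) and Arhgef (−0.34 over 21).

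The brighter Bach2 probe read lower in MPPs with the Bach2 vector than with the bZIP-deleted one, while the second probe, dim on 3 of 6 arrays, differed by 0.29. Swapped vector labels would put the heme and oxidative stress genes, which Bach proteins are known to repress, higher in the arrays labelled Bach2. The median of that list was −1.05 with 0 members higher, which argues against a swap as far as that repression is taken as given. It does not settle the label field that names only a GFP vector, since the difference can come from either form of Bach2. A brighter probe that does not read the vector transcript may account for its low levels, since its highest MPP array differed from the lowest wild-type LSK array by −3.10. The second probe read −4.47 and −4.76 in the MPP groups and −6.83 in wild-type LSK cells. It was dim on 3 of the 6 MPP arrays and on all wild-type LSK arrays, so these levels do not show whether it reads the vector. Whether endogenous Bach2 was lowered stays open, as the difference between the vectors did not pass in the main fit and passed in only 2 of 17 alternatives.

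Knockout replicate 3 stood apart from the other LSK arrays, and more neutrophils and macrophages together in this sample were argued against, because the neutrophil median of replicate 3 minus the mean of replicates 1 and 2 lay at percentile 22.0 of 10000 expression-matched random lists (monocyte-macrophage 98.7). The eosinophil (1.06), mast cell and basophil (0.57), MHC class II (0.59) and megakaryocyte-platelet (0.41) medians were high and the B lineage median low (−1.13), and although sorting for lineage-negative c-kit-positive cells would remove most mature cells, a share of such cells was not tested. Within the Sca-1-positive sort, a higher share of cells that express granulocyte-monocyte progenitor genes and a lower share of lymphoid and stem cell progenitors may be present. The medians were 1.10 for the first list, −1.07 for early lymphoid and −0.77 for stem cell genes. As 1 array was on its slide, slide and scan cannot be told apart from the sample, and a difference between mice or in the effect of the knockout was not tested.

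The plasma cell list was lower in knockout LSK cells. Plasma cells in the wild-type samples are a candidate source. Over the 3 wild-type arrays the mean pairwise correlation of the 9 members was 0.733 (percentile 99.9 of 10000 expression-matched random lists, value 99.94). Not all members varied alike, as Xbp1 and Edem1 were highest in wild-type replicate 2 and the other members in replicate 1. With 3 arrays this test cannot tell plasma cells from shared regulation of these genes within LSK cells. Edem1, the 1 member with a positive difference, read 2.08, 2.13 and 1.79 in wild type and 1.99, 2.09 and 2.85 in the knockout. Jchain read 6.23, 5.89 and 5.03 in the wild-type arrays and 3.44, 2.56 and 3.47 in the knockout, Mzb1 3.97, 2.43 and 1.46 against 0.30, −0.21 and −1.05, and Xbp1 5.06, 5.25 and 5.01 against 4.89, 4.85 and 5.01, while sorting for lineage-negative c-kit-positive cells would remove most mature cells. Fewer mature lymphoid cells of all kinds in the knockout could not be settled by the rule used. The B lineage median was −0.0602 and the T and NK lineage median −0.194, against −1.72 for plasma cell genes. Neither lineage list passed camera (adjusted p = 0.465 for both). The rule took as its margin the SD of 0.884 over B lineage members, a spread between genes and not an error of the median. Within the slide the medians were 0.20 for B lineage, −0.14 for T and NK lineage and −1.34 for plasma cell genes. An effect of the knockout on the expression of these genes stays open and untested.

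The 6 arrays of a comparison can be split in 10 ways, too few for a share under 0.05. In MPPs the real split gave 928 genes and 14 lists, and the highest of the other splits 0 genes and 7 lists, so that 1 split reached each. In LSK cells the real split gave 10 genes and the highest other 0 (1 split), and 7 lists against 10, with 4 splits giving at least 7. The correlation of gain and loss was −0.151 in the real split of the LSK arrays and at most 0.113 in size in the others (1 split).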
